A study of Mus musculus with 2 samples.

How the data were processed

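Liver tissue of mice labelled as Slc22a18 knockout or wild type was measured by single-cell RNA sequencing, with 1 library per genotype and therefore no replicates. Strain, age, sex, number of animals and deleted exons are not given in the sources used here. Per the labels, libraries were made with the Chromium Single Cell 3' v3 kit. The submitters' processing notes name Cell Ranger, STAR and the mm10 build, and the matrices are from Cell Ranger 8.0.1 per the file headers. The deposited values are counts, raw UMI counts per gene and cell barcode without normalization, and the barcodes present had at least 500 UMIs. The other deposited files hold gene identifiers and barcodes. The 33696 gene identifiers were placed with GENCODE vM21 on GRCm38, in which 1684 identifiers were absent, so the annotation used for counting differs from it.

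The knockout-labelled library held 103478998 UMIs in 11741 barcodes and the wild-type library 105556354 UMIs in 12796 barcodes. Cells were kept with at least 500 UMIs, at least 300 detected genes and at most 20% mitochondrial UMIs. Doublets were scored by a Scrublet implementation in scanpy 1.11.5, in each library alone, with an expected rate of 8% and 30 components. Its automatic threshold gave 0 calls in the knockout-labelled library, so the threshold of the wild-type library, 0.286, was used for both, which gave 366 and 394 calls (3.15% and 3.12%). Removal left 11101 and 12040 cells. Free RNA was not subtracted. It remains a limit, and the share of a gene in a class that should lack it stands beside shares of cells.

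Both libraries were clustered together without integration, on 2000 variable genes (Slc22a18, mitochondrial, ribosomal protein, haemoglobin, sex-linked and receptor segment genes left out) and 30 components with 15 neighbours, by the Leiden method at resolution 1.0. The 33 clusters were named by marker lists fixed beforehand, from the mean log2 ratio of each list's genes to the median cluster. A cluster stayed unnamed when its median doublet score was at least 0.15, when under 3 markers were found in 10% of its cells, or when its second class scored at least 1.5 and at least 0.70 of the first. It also stayed unnamed when its 10 leading genes held more markers of another class, or none of its own at low UMIs. Unnamed clusters held 12.7% and 14.5% of the cells. Class names stand for cells that carry the markers. Clusters differed between the libraries in hepatocytes, with cluster 16 the largest in the knockout-labelled library and cluster 9 in the wild-type library. Several ways of scoring the marker lists were tried, and the way used, the limit of 0.15, the value 0.70 (at first 0.75) and the shared doublet threshold were chosen after seeing the data.

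Gene counts were summed over the cells of a class in each library and scaled to counts per 1000000 UMIs of the class (CPM). Ratios of CPM were given with exact Clopper-Pearson 95% intervals from the 2 counts, CPM with exact Poisson intervals, and shares of cells with exact binomial (Clopper-Pearson) intervals. Ratios of shares carry intervals from a normal approximation on the log scale. These cover counting error only, since cells are not replicates, and no p-value was computed. Log2 ratios were computed with 0.5 added to each sum, and a floor of 3 counts was used against a sum of 0. The 8 classes with at least 100 cells in each library were compared. A gene passed the size rule with at least 50 summed UMIs, a CPM ratio of at least 2, an interval excluding 1, and a UMI in at least 5% of the class's cells in the higher library. Genes under 10% of the level of the highest class, in both libraries, were set aside as possible free RNA.

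Genes were named by a rule fixed before the data were examined. It took the 10 largest ratios in each direction in the 4 largest classes and the 3 largest in the others (mitochondrial, ribosomal protein, haemoglobin and receptor or immunoglobulin variable segment genes left out), members of gene lists past the size rule (up to 4 in each direction) or otherwise the 2 members with the most UMIs, and the imprinted neighbours of Slc22a18. Haemoglobin genes, S100a8 and S100a9, outside that rule, were looked at after seeing the data. The 35 gene lists were fixed beforehand too and were described by the median log2 ratio of members with at least 20 UMIs and its percentile among 10000 random lists of the same size, matched on expression in 20 bins. Lists with fewer than 5 measured members were given gene by gene. A list of 19 clock genes was added after seeing the data, and the interferon, dissociation, sinusoidal, unfolded protein and type 2 lists were read in further classes then. Shares of cells with a UMI were computed after thinning each cell to the 20th percentile of UMIs of its class, leaving out shallower cells, and without thinning.

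The procedure was tested on simulated data, Poisson draws around the rates of both libraries together, with genes found in at least 10% of the cells changed. Shares of cells with a UMI were held fixed, no gene was set aside as free RNA, and unchanged genes differed by counting error alone. The simulation therefore cannot show how often variation between libraries carries a gene over the rule. A change of 1.5-fold lies below the limit of 2 by construction. Genes changed 2.5-fold or 4-fold up, or to 0.4 or 0.25 of their level, were recovered in 40 of 40 cases each in hepatocytes and endothelial cells, genes changed 1.5-fold in 0 of 40, and unchanged genes in 0 of 14391 and 0 of 13741. Intervals covered the true ratio in 95.4% and 95.7% of cases. Lists with no change lay outside percentiles 2.5 to 97.5 in 14 and 13 of 200 cases, and changed lists lay above in 50 of 50.

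Alternatives fixed beforehand were other limits on mitochondrial UMIs (10% and 50%), detected genes (1000) and doublets, resolutions of 0.5 and 2.0, each library clustered alone, TMM factors (edgeR 4.0.16 in R 4.3.3), a median ratio, each cell weighted equally, other limits of the size rule and other thinning. Added after seeing the data were the 2 other limits on naming clusters, clusters given the same weights in both libraries (their share of the UMIs of the class), stellate-like cells without cluster 20, T cells without cluster 22, and the clock list. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and igraph 0.11.9 were used.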

Results

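Liver tissue of 2 groups of mice was measured by droplet single-cell RNA sequencing, with 1 library labelled as lacking Slc22a18 and 1 library labelled wild type. The series title names the imprinted transporter gene Slc22a18, a beta-catenin and Ascl2 axis, allergy, short stature and fatty liver as its subjects. The knockout-labelled library held 103478998 UMIs in 11741 barcodes and the wild-type library held 105556354 UMIs in 12796 barcodes. After filtering, 11101 cells with a median of 5841 UMIs and 12040 cells with a median of 5362 UMIs were kept. With 1 library per genotype there were no replicates, so no test was run. The 95% intervals below cover counting error only and are exact apart from those of share ratios, and a difference between the libraries cannot be assigned to genotype rather than to animal, background or dissociation. A gene was named as higher or lower by a rule on size: a ratio of at least 2, at least 50 UMIs, an interval that excluded 1, and a UMI in at least 5% of the cells of the class in the higher library.

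The comparison of Slc22a18 asks what the labels mean at the level of the targeted gene. Slc22a18 (ENSMUSG00000000154, GRCm38 chromosome 7, 143473736 to 143499334, plus strand) was detected in both libraries. Over all kept cells, 2038 UMIs in the knockout-labelled library (21.3 counts per 1000000 UMIs, CPM, 20.4 to 22.3) stood against 2363 UMIs in the wild-type library (24.3 CPM, 23.4 to 25.3), a ratio of 0.876 (0.825 to 0.930). In hepatocytes, where the gene was highest, the ratio was 0.926 (0.860 to 0.997), from 1373 and 1503 UMIs. It was 0.374 (0.242 to 0.563) in liver endothelial cells, from 32 and 95 UMIs, and 0.473 (0.353 to 0.630) in Kupffer cells, from 75 and 141 UMIs. In the small class of cholangiocyte-like cells, 9 UMIs against 33 gave 0.234 (0.0986 to 0.5004), and in stellate-like cells 330 against 284 gave 1.09 (0.927 to 1.28). The 2 stellate-like clusters with at least 20 UMIs had ratios of 0.256 and 0.860, so the pooled 1.09 depends on the mix of clusters. Hepatocyte clusters ranged from 0.749 to 1.51, with 3 of 4 lower. Unnamed cells, with 174 against 238 UMIs, had 0.657 (0.537 to 0.802). Of the compared classes, Kupffer cells alone passed the size rule for this gene, and they did not at clustering resolution 0.5 (log2 ratio -0.50 against -1.08) or with each cell weighted equally (-0.97); in endothelial cells under 5% of the cells held a UMI. The endothelial levels, 1.34 and 3.58 CPM, also lay under 10% of those in hepatocytes and may be free RNA. The counts therefore did not verify the label, and a 3' tag outside a deleted part would check nothing, since the sources used here do not name the deleted exons. Every direction below is a direction between the library labelled knockout and the library labelled wild type.

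**Figure D1:**
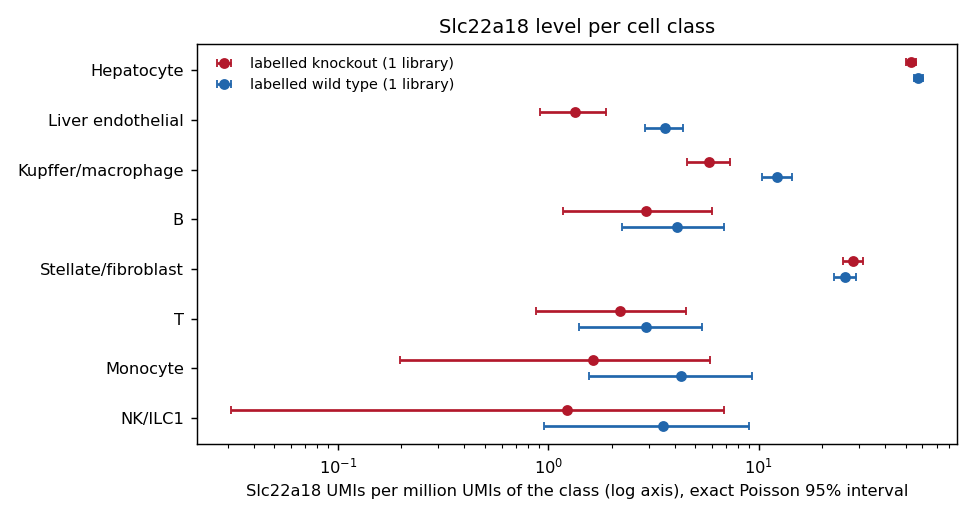
Slc22a18 CPM on a log axis, for the 8 compared cell classes in the 2 libraries, with exact Poisson 95% intervals. The gene is near 53.1 and 57.3 CPM in hepatocytes of the 2 libraries, while the intervals of the 2 libraries separate in endothelial and Kupffer cells.

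The imprinted region was read as a list of 20 genes, Slc22a18 included, with 16 measured. None passed the size rule over all kept cells, and their median log2 ratio was -0.053 (percentile 10.4 among 10000 random lists of matched expression). Kcnq1ot1, the long noncoding RNA of the imprinting centre, had a ratio of 1.002 (0.976 to 1.03), and Cdkn1c, a cyclin-dependent kinase inhibitor, had 0.948 (0.901 to 0.998). Phlda2 had a ratio of 2.32 (1.70 to 3.18) from 139 and 61 UMIs, in fewer cells than the size rule asks for. H19 differed by class, with a ratio of 1.91 (1.52 to 2.40) in hepatocytes from 224 and 119 UMIs and 0.144 (0.0664 to 0.279) in endothelial cells from 10 and 77 UMIs. Neither met the size rule, and the difference between the classes was not tested. Ascl2, the transcription factor named in the title, gave 5 and 10 UMIs over all kept cells, a ratio of 0.508 (0.136 to 1.63), so no difference was detectable at this depth.

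The comparison of cell composition asks which liver cell types differed in their share. Cells of the 2 libraries fell into 33 clusters, of which 28 were named as 13 classes by markers. Kupffer cells, the resident macrophages of the liver, made up 13.03% (12.4 to 13.7) of the cells of the knockout-labelled library and 10.4% (9.86 to 11.0) of the wild-type library, a ratio of 1.25 (1.17 to 1.35). B cells made up 6.57% (6.11 to 7.04) and 8.26% (7.78 to 8.77), a ratio of 0.795 (0.725 to 0.871). NK/ILC1 cells, the innate lymphocytes, made up 1.29% (1.09 to 1.52) and 1.79% (1.56 to 2.05), and neutrophils 0.595% (0.460 to 0.756) and 0.831% (0.676 to 1.01). Of the non-hepatocytes, the Kupffer ratio was 1.28 (1.19 to 1.37) and the B cell ratio 0.810 (0.740 to 0.887). Hepatocytes (28.5% and 27.2%), endothelial cells (23.4% and 23.1%), stellate-like cells (5.98% and 5.81%), T cells (3.81% and 4.13%) and monocytes (1.74% and 1.74%) had ratios between 0.923 and 1.05. Unnamed clusters held 12.7% and 14.5% of the cells, with cluster 8, which carried markers of 2 classes at low depth, taking 5.32% and 8.20%. Cluster 11, with markers of T and NK/ILC1 cells, took 3.92% and 3.11%, a ratio of 1.26 (1.10 to 1.44), opposite to the ratios of the 2 named classes. With each library clustered alone the NK/ILC1 ratio turned to 1.09 and the T cell ratio moved to 1.80, so no direction is given for these 2 shares.

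**Figure D2:**
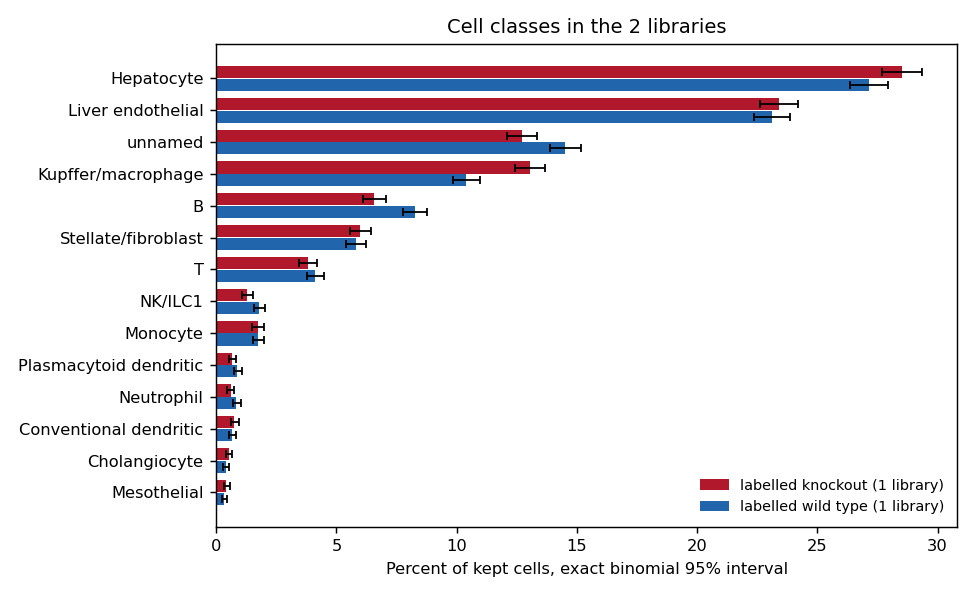
Percent of kept cells in each named class and in unnamed clusters, for the 2 libraries, with exact binomial 95% intervals that cover counting error only. Kupffer cells took 13.03% of the knockout-labelled library against 10.4%, and B cells 6.57% against 8.26%.

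Some genes passed the size rule in at least 3 cell types. Slc15a2, a transporter of small peptides (ENSMUSG00000022899, GRCm38 chromosome 16, 36750177 to 36784962, minus strand), was higher in the knockout-labelled library in 8 of 8 classes. In endothelial cells 2318 UMIs stood against 1 UMI, a ratio of 2571 (461 to 101588). In B cells 460 stood against 13, a ratio of 50.5 (29.2 to 95.5), and in hepatocytes 553 stood against 0, at least 187-fold higher when 3 counts are taken as the floor. The predicted gene Gm56626 was higher in 5 classes, with 4.77-fold (3.56 to 6.50) in endothelial cells, and Eps8l1, a regulator of the actin skeleton, was higher in 3, with 4.55-fold (3.49 to 5.99) in endothelial cells. Cdk5rap1, an enzyme that modifies mitochondrial transfer RNA, was higher in endothelial, B and T cells. Mid1, an X-linked ubiquitin ligase, was lower in Kupffer cells, B cells and monocytes, Igfbp1 in hepatocytes, Kupffer cells and stellate-like cells, and the heat shock gene Hspa1b in T cells, monocytes and NK/ILC1 cells. Of these 7 genes 6 could be placed on the annotation, on 6 chromosomes, and none lay within 20 Mb of Slc22a18.

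**Figure D3:**
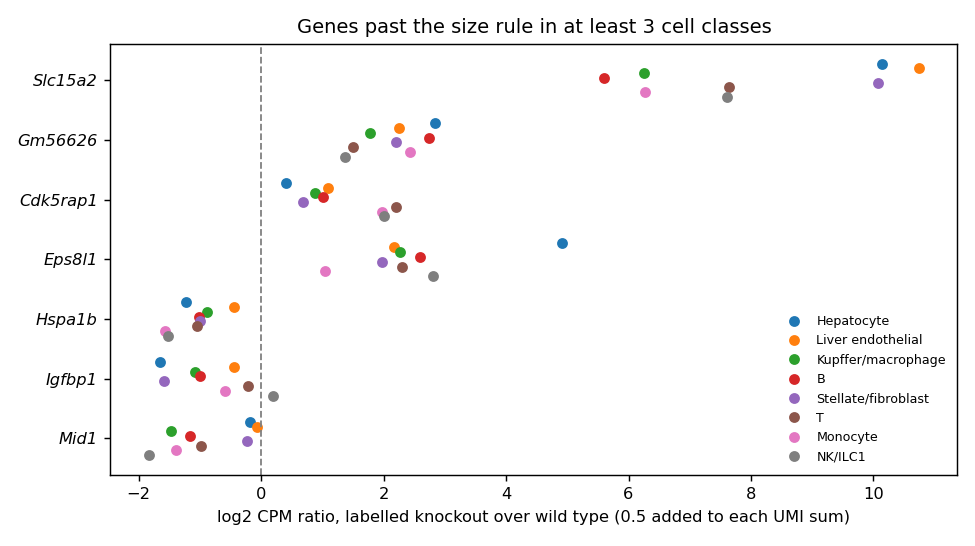
The log2 ratio of CPM between the library labelled knockout and the library labelled wild type, with 0.5 added to each UMI sum, for the 7 genes past the size rule in at least 3 cell classes; each point is a class. Slc15a2 lies above 5 in every class, where values against 0 or 1 UMI depend on the amount added, and Gm56626 and Eps8l1 lie above 1 in every class.

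The comparison within hepatocytes addresses the fatty liver, growth and beta-catenin subjects of the title. In the knockout-labelled library 42 genes were higher and 21 lower. Onecut1, a hepatocyte transcription factor, was 4.55-fold higher (4.27 to 4.85), Myc, the growth-promoting transcription factor, 7.91-fold (6.33 to 9.98), and Gadd45g, a stress- and cytokine-induced gene, 4.23-fold (3.92 to 4.57). G6pc, the glucose-6-phosphatase of glucose release, was 4.003-fold lower (3.89 to 4.12), and Igfbp1, a fasting-induced binding protein of insulin-like growth factors, 3.13-fold lower (2.87 to 3.42). Slc25a30, a mitochondrial carrier, was 5.43-fold higher (4.95 to 5.97) and Acot3, a peroxisomal thioesterase, 4.09-fold (3.4998 to 4.80). The X-linked genes Xlr3b (381 and 1 UMIs, ratio 386, 68.9 to 15301), Xlr4a (203 and 2 UMIs, ratio 103, 28.1 to 856) and Xlr3a (7.48-fold, 5.86 to 9.67), and the predicted gene Gm33459 (11.6-fold, 8.05 to 17.2), completed the largest differences upward, after Slc15a2.

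Downward, the largest differences after G6pc were in Egfros (3.94-fold lower, 3.66 to 4.24), Efna1, an ephrin ligand (3.69-fold, 3.46 to 3.94), Igfbp1, and Serpina1e, a protease inhibitor (2.94-fold, 2.85 to 3.02). Cib3 (2.83-fold), the stress cytokine Gdf15 (2.51-fold), Cux2 (2.47-fold), Zfp951 (2.34-fold) and Nr0b2 (2.27-fold) followed. Within the hepatocyte clusters, G6pc was lower in 4 of 4 clusters and Myc higher in 4 of 4, while Onecut1 and Slc25a30 were higher in 3 of 4. Cluster 16 held the largest part of the hepatocytes of the knockout-labelled library (40.4% against 31.0%) and cluster 9 that of the wild-type library (35.2% against 32.4%). The leading genes of cluster 16 included Lgr5, of the pericentral rim, and Cyp7a1. Those of cluster 9 included the periportal genes Etnppl, Hsd17b6, Hal and G6pc. Pooled values of zoned genes may depend on this mix. RNA of hepatocytes was found in other cells of both libraries, so free RNA limits the values of hepatocyte genes in the other classes. Free RNA was not subtracted, and whether RNA of other classes adds to the hepatocyte values is open. Myc, for example, was at 425% of its hepatocyte level in another class of the knockout-labelled library.

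**Figure D4:**
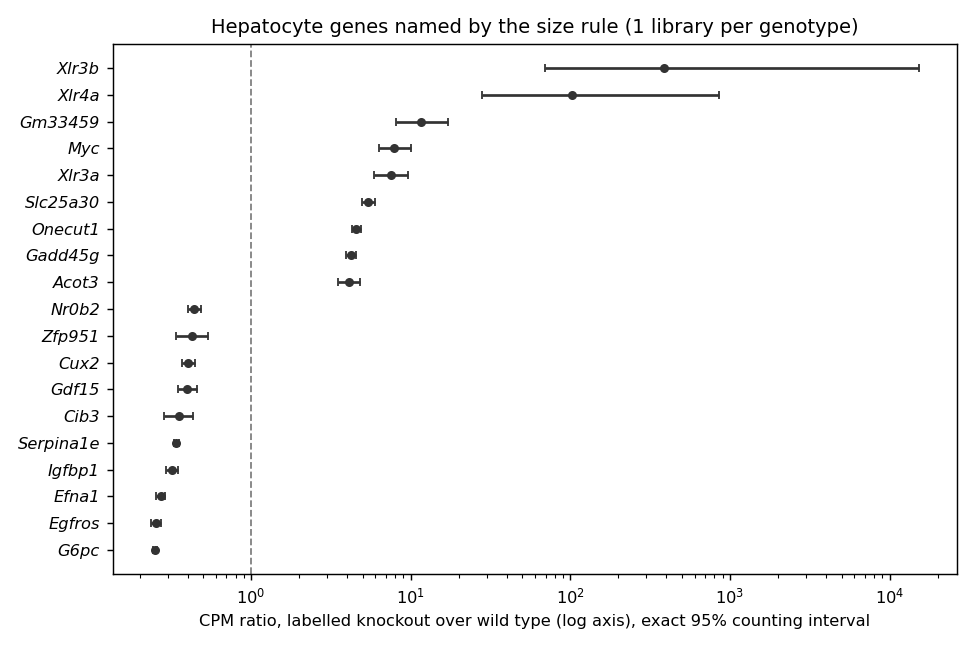
Ratio of CPM in hepatocytes, library labelled knockout over library labelled wild type, on a log axis with exact 95% counting intervals, for the largest differences in each direction past the size rule. Slc15a2, with 0 UMIs in the wild-type library, is not drawn; Myc lies at 7.91 and G6pc at 0.2498.

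Groups of hepatocyte genes named by the study's subjects stayed near the level of matched lists. Of 17 measured targets of Wnt and beta-catenin, Myc was higher and none lower, and their median log2 ratio was -0.038 (percentile 8.15). The 23 genes of lipogenesis had a median of -0.013 (percentile 6.19) and none passed the size rule; Mlxipl, a carbohydrate-responsive transcription factor, had a ratio of 1.10 (1.08 to 1.12) and Thrsp 0.802 (0.786 to 0.818). The 23 genes of lipid droplets and lipid uptake had a median of 0.026 (percentile 29.6), which lay below 0 under 4 of 14 alternatives, with none past the rule; Fabp1, the liver fatty acid binding protein, had 0.782 (0.776 to 0.787). The 27 genes of fatty acid oxidation had a median of -0.00525 (percentile 7.71) and none past the rule. Of 23 genes of the growth hormone and IGF axis, 2 were higher and 1 lower, with a median of -0.023 (percentile 7.08). The feedback inhibitors of cytokine receptor signalling Socs2 (3.59-fold, 3.29 to 3.93) and Cish (2.40-fold, 2.15 to 2.67) were higher and Igfbp1 lower. The medians of the Wnt, fatty acid oxidation and growth hormone lists changed sign under some settings, so no direction is given for these lists.

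Other hepatocyte groups stood further out. Bile acid synthesis and transport had a median log2 ratio of 0.16 (percentile 99.2) over 19 genes, with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 2.15-fold higher (2.06 to 2.24) and Nr0b2, its repressor, lower. Gluconeogenesis and glycolysis had a median of -0.15 (percentile 0.460) over 18 genes, with G6pc and Tat, tyrosine aminotransferase (2.15-fold lower, 2.11 to 2.19), past the rule. Genes of the periportal zone had a median of -0.22 (percentile 0.08), with the same 2 genes past the rule among 20, while those of the pericentral zone had -0.0050 (percentile 11.4), of either sign under other settings, with none. The share of hepatocytes with a UMI of Cyp2e1, a pericentral enzyme, was 62.6% (60.7 to 64.4) and 53.8% (51.8 to 55.7) after thinning to 2516 UMIs, and 70.2% and 62.2% without thinning. T cells, which should lack it, gave 22.6% and 19% at 4432 UMIs and 33.8% and 25.4% without thinning, at median depths of 6308 and 5912 UMIs against 5284 and 4812 in hepatocytes. Lgr5, a Wnt target of the pericentral rim, was found in 8.47% (7.44 to 9.60) and 7.27% (6.29 to 8.36) of thinned hepatocytes, and in 17.5% and 14.0% without thinning, against 0.593% and 0.5% of thinned T cells and 0.946% and 1.21% without. Axin2 (3.27% and 2.66%) and Glul (11.0% and 11.2%) lay below their shares in T cells (5.34% and 3.75%, 16.9% and 16.3%), which were thinned to the larger depth. Without thinning, Axin2 was found in 8.82% and 7.95% of hepatocytes and 6.62% and 6.04% of T cells, and Glul in 22.5% and 21.9% against 23.2% and 22.5%, so background is left open for both. Cyp2f2, a periportal enzyme, gave 42.9% and 42.0% thinned and 58.6% and 55.5% without, with 12.2% and 10% of thinned T cells and 16.8% and 13.1% without. By hepatocyte cluster, the CPM ratio of Cyp2e1 was above 1 in 4 of 4 clusters (1.002 to 1.28). That of Glul was below 1 in 4 of 4 (0.551 to 0.901). The ratio was above 1 in 2 of 3 clusters for Lgr5, 1 of 3 for Axin2 and 2 of 4 for Cyp2f2. Slc22a18 itself was found in 13.3% (12.0 to 14.6) and 13.8% (12.5 to 15.2) of thinned hepatocytes and in 28.3% and 27.6% without thinning, against 1.48% and 0.75% of thinned T cells and 1.65% and 1.61% without.

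The medians of the lists of sex-biased liver genes lay on opposite sides of 0 in hepatocytes, while 16 of 20 female-biased and 14 of 17 male-biased genes passed the size rule in neither direction. The 20 female-biased genes had a median log2 ratio of 0.29 (percentile 100), with Acot3, Slc22a26 (2.23-fold, 2.005 to 2.49) and Fmo2 (2.01-fold, 1.86 to 2.18) higher and Cux2 lower. The 17 measured male-biased genes had a median of -0.38 (percentile 0), with Serpina1e lower and Keg1 (2.12-fold, 2.01 to 2.24) and C8b (2.10-fold, 1.959 to 2.25) higher. Under the alternatives the male-biased median lay between -0.44 and -0.21, and the female-biased median between 0.24 and 0.32. In both libraries Xist, the RNA of the inactive X chromosome, was abundant (1715 and 1488 CPM), and the Y-linked genes Eif2s3y, Kdm5d and Uty gave 0 to 4 UMIs over all kept cells, while Ddx3y, also Y-linked, gave 75 and 64. Acute phase genes lay at the edge of the matched lists (median 0.15, percentile 97.6), with Fga, a fibrinogen chain (2.11-fold, 2.06 to 2.16), and Mt2, a metallothionein (2.67-fold, 2.38 to 2.996), higher. The unfolded protein response had a median of -0.35 (percentile 0), lipoprotein assembly -0.28 (percentile 0.0300) and xenobiotic metabolism -0.13 (percentile 0.180), with none past the rule. Herpud1, a gene of the unfolded protein response, had a ratio of 0.808 (0.782 to 0.835), while its regulator Xbp1 had 1.76 (1.67 to 1.85). Mitochondrially encoded transcripts, a sign of cytoplasm carried into the droplet, had a median of -0.49 beside these lists. This median turned to 0.041 with doublet calls kept, and was -0.071 when up to 10% mitochondrial UMIs were allowed and -0.19 with each cell weighted equally. With the hepatocyte clusters given the same weights in both libraries the medians shrank to -0.061 for the periportal list, -0.017 for lipoprotein assembly, -0.018 for xenobiotic metabolism, -0.18 for the unfolded protein response and 0.068 for bile acids.

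The comparison within endothelial cells asks how the liver vasculature differed. There 9 genes were higher and 3 lower; with a limit of 0.75 on the second class in naming clusters, 9 were higher and 13 lower, with 10 shared. Cyp26b1, an enzyme that degrades retinoic acid, was 4.34-fold higher (4.16 to 4.52), from 11278 and 2885 UMIs, and was higher in 6 of 6 clusters. Cdk5rap1 was 2.13-fold higher (1.76 to 2.58), and the haemoglobin gene Hbb-bs, a sign of blood cell RNA, was 2.23-fold higher (2.17 to 2.28). The unannotated transcript G530011O06Rik (2.69-fold, 2.15 to 3.38), Csmd1, a complement regulator (2.35-fold, 2.09 to 2.65), and the heat shock gene Hspb1 (2.01-fold, 1.84 to 2.20) were lower. The interferon response had a median log2 ratio of 0.18 (percentile 100) over 31 genes with none past the size rule; Cxcl10, an interferon-induced chemokine, had a ratio of 1.30 (1.27 to 1.32). The 23 sinusoidal and vascular genes had a median of 0.0033 (percentile 58.5), with Stab2, a scavenger receptor of sinusoidal cells, at 0.979 (0.969 to 0.989). Transcripts of hepatocytes in these cells had a median of -0.084 (percentile 0.210). Of the 8 genes other than those of haemoglobin, Cdk5rap1 and Hspb1 missed the size rule under at least 1 of 13 alternatives.

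The comparison within Kupffer cells addresses the inflammatory side of the liver. There 8 genes were higher and 10 lower, and 13 of these 18 genes missed the size rule under at least 1 of 13 alternatives. At clustering resolution 0.5 24 genes were higher and 13 lower, with each cell weighted equally 24 and 32, and with no limit on the doublet score 7 and 12, with 8, 14 and 8 genes shared. Cxcl9, a chemokine induced by interferon gamma, was 2.59-fold higher (2.15 to 3.13) and Zfas1, a small nucleolar RNA host gene, 2.03-fold (1.86 to 2.22). Mid1 was 2.79-fold lower (2.40 to 3.26), though not in each cluster, with ratios of 0.310 (0.262 to 0.365) in cluster 14 and 1.61 (0.916 to 2.91) in cluster 19. The chaperone Hsph1 was 2.40-fold lower (2.18 to 2.64), though in 2 of 3 clusters only, with ratios from 0.414 to 1.02. The DNA replication genes Mcm5 (2.24-fold, 1.75 to 2.88), Hells (2.20-fold, 1.62 to 3.01) and Mcm2 (2.08-fold, 1.61 to 2.70) were lower too. Also higher were Slc15a2 (1071 and 12 UMIs, ratio 79.4, 45.3 to 154.1), Eps8l1 (4.95-fold, 2.89 to 9.03), Gm56626 (3.48-fold, 2.21 to 5.70), 4833418N02Rik (2.25-fold, 1.53 to 3.36), Vars2 (2.16-fold, 1.44 to 3.30) and Peak1os (2.001-fold, 1.36 to 2.98). Also lower were Rad18 (2.19-fold, 1.59 to 3.05), Igfbp1 (2.13-fold, 1.43 to 3.23), Slc7a6 (2.07-fold, 1.43 to 3.05) and Tmx4 (2.07-fold, 1.55 to 2.78). Genes of inflammatory cytokines and NF-kB had a median log2 ratio of 0.36 (percentile 100) over 21 genes, with Cxcl2 at 1.33 (1.30 to 1.36) and Nfkbia at 1.27 (1.24 to 1.30). The interferon response had 0.15 (percentile 100) over 31 genes and antigen presentation by MHC class II 0.14 (percentile 99.6) over 14 genes. Elsewhere the interferon median was 0.096 (percentile 87.25) in T cells, -0.20 (percentile 0.610) in monocytes, -0.15 (percentile 1.595) in stellate-like cells, -0.15 (percentile 2.93) in B cells and -0.19 (percentile 5.21) in NK/ILC1 cells. It turned to 0.035 in monocytes over members with at least 100 UMIs and to 0.24 in stellate-like cells without cluster 20. In B cells it lay between -0.47 and 0.14 under the alternatives. The 17 genes of lipid-associated macrophages had a median of -0.0041 (percentile 55.5) with none past the rule, and Apoe, a lipid carrier, had 0.746 (0.740 to 0.752). Proliferation genes had -0.22 (percentile 0.370). Mki67, a marker of dividing cells, was found in 1.72% (1.05 to 2.64) and 2.11% (1.31 to 3.20) of Kupffer cells thinned to 1326 UMIs. The order was the other way at 8488 UMIs (13.2% and 11.4%) and without thinning (12.4% and 10.5%). With no limit on the doublet score of a cluster, the log2 ratio of Cxcl9 moved from 1.37 to 0.64 and that of Mid1 from -1.48 to -0.82, and the medians were 0.21 for the NF-kB list and 0.025 for MHC class II. The MHC class II median was 0.057 with each library clustered alone, and the log2 ratio of Tmx4 turned to 0.11 at clustering resolution 0.5.

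In B cells 7 genes were higher and 7 lower, and these counts depended on the processing. With no limit on the doublet score 136 were higher and 20 lower, 6 of them shared. Of the 14 genes 11 missed the size rule under at least 1 of 13 alternatives. Up to 50% mitochondrial UMIs gave 63 and 47 with 4 shared, and each library clustered alone gave 29 and 8 with 11 shared. Slc15a2 and Gm56626 (6.90-fold, 3.66 to 14.1) were highest, and Iglc3, a constant gene of the lambda light chain, was 2.61-fold lower (2.43 to 2.79). Mid1 was 2.25-fold lower (1.51 to 3.44) and Dynlt1f, a dynein light chain, 2.80-fold lower (1.54 to 5.45). The other higher genes were Cpeb3 (2.47-fold, 1.55 to 4.02), Slc39a11 (2.30-fold, 1.49 to 3.59), A930024E05Rik (2.27-fold, 1.43 to 3.66), Ppfibp2 (2.05-fold, 1.56 to 2.70) and Cdk5rap1 (2.03-fold, 1.25 to 3.32). The other lower genes were Serpina1e (2.66-fold, 2.06 to 3.47), which may be free hepatocyte RNA at 31.7 and 84.3 CPM against 231 and 679 CPM in hepatocytes, Gm15327 (2.18-fold, 1.26 to 3.94), Frmd6 (2.14-fold, 1.29 to 3.68) and Ago4 (2.03-fold, 1.32 to 3.21). The constant genes of immunoglobulins had a median log2 ratio of 0.085 (percentile 97.6) over 8 genes, which turned to -0.40 with no limit on the doublet score, -0.15 up to 50% mitochondrial UMIs and -0.026 with each cell weighted equally, so no direction is given. The log2 ratio of Ago4 turned to 0.075 and 0.079 under the first 2 of these settings, and up to 50% mitochondrial UMIs those of Cpeb3, Slc39a11, Ppfibp2 and Mid1 were 0.13, 0.45, 0.15 and -0.47. The log2 ratio of Iglc3 was -0.33 with each library clustered alone, against -1.38, and Iglc3 differed by 1.18-fold and 17.5-fold in the 2 B cell clusters.

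In stellate-like cells, the matrix-producing and vitamin A-storing cells, 144 genes were higher and 52 lower, with each library clustered alone 243 and 89 with 180 shared, and with the same cluster weights in both libraries 56 and 26 with 72 shared. Matrix and fibrosis genes had a median log2 ratio of -0.56 (percentile 0) over 24 genes, with Sparc at 0.699 (0.687 to 0.711) and Col3a1, a fibrillar collagen, at 0.667 (0.651 to 0.684), and none past the size rule. Hepatocyte transcripts had a median of 0.31 (percentile 99.8) in the same cells, with Fgb, a fibrinogen chain, 2.60-fold higher (2.49 to 2.71). Cluster 20, with a median of 1.25% mitochondrial UMIs, held 57.5% and 50.6% of the class. Without it 58 genes passed the rule, 20 of them shared with the full class, and the medians were -0.16 for matrix genes and 0.077 for hepatocyte transcripts. Sinusoidal and vascular genes (-0.38, percentile 0), dissociation genes (-0.32, percentile 0) and the unfolded protein response (-0.34, percentile 0.0300) were low in the full class too, and had -0.0048, 0.12 and -0.056 without cluster 20. The matrix median is therefore not set apart from cell mix or handling. Fam180a was 3.48-fold lower (2.48 to 4.95) and the light chain gene Iglc1, with 27 UMIs against 2074, 81.9-fold lower (56.2 to 125), although its log2 ratio was -1.06 without cluster 20 and -0.45 with each library clustered alone, against -6.33, and it missed the size rule under 4 of 14 alternatives. G530011O06Rik (3.51-fold, 2.01 to 6.45) was lower too, and the largest differences upward were Slc15a2 (572 and 0 UMIs, at least 178.7-fold), Gm33459 (74 and 1 UMIs, ratio 69.4, 12.1 to 2777) and Xlr3b (106 and 3 UMIs, ratio 33.1, 11.03 to 163.2). Gm33459 and Xlr3b passed the rule in hepatocytes too. So did other genes past it in stellate-like cells, such as Cyp7a1, Fga, G6pc and Onecut1, and hepatocyte RNA may give these values. Without cluster 20 the log2 ratio of Gm33459 was 1.93 against 5.54 and that of Xlr3b 2.88 against 4.83, and 4 of the 6 genes named by ratio missed the size rule under at least 1 of 14 alternatives.

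The comparison within T cells addresses the allergy subject and the axis of Ascl2. There 154 genes were higher and 19 lower. With each library clustered alone 275 were higher and 15 lower, 116 of them shared, and up to 50% mitochondrial UMIs 33 and 18 with 21 shared. Cluster 22, whose leading genes are those of dividing cells, held 19.1% of the T cells of the knockout-labelled library (81 cells) and 5.43% of those of the wild-type library (27 cells). With the T cell clusters given the same weights in both libraries 39 genes passed the rule, 19 higher and 20 lower, so most of the higher genes reflect the mix of T cells. Of 21 proliferation genes 13 were higher, with a median log2 ratio of 1.12 (percentile 100), which was 3.75 and 0.35 under these 2 settings; the kinetochore gene Nuf2 was 5.22-fold (3.07 to 9.38) and Ccnf, a cyclin, 5.25-fold higher (2.71 to 11.1). The granzymes of cytotoxic cells Gzma (4.06-fold, 3.67 to 4.50), Gzmk (3.43-fold, 2.23 to 5.45) and Gzmb (3.0-fold, 2.69 to 3.35) were higher, with a median of 0.41 (percentile 100) over 19 cytotoxic genes. Genes of T follicular helper cells had a median of -0.26 (percentile 0.0100) over 14 genes with none past the rule, beside -0.27 (percentile 0) for dissociation genes in the same cells, and Tcf7, a transcription factor of the Wnt pathway, had 0.740 (0.673 to 0.814). Without cluster 22, 33 genes passed the rule, 15 of them shared, and the medians were -0.098 for proliferation, 0.045 for cytotoxic genes and -0.060 for follicular helper genes, and the log2 ratio of Ccnf turned to -0.79. Up to 50% mitochondrial UMIs the log2 ratio was 0.57 for Nuf2 and 0.19 for Ccnf. Regulatory T cell genes had a median of 0.033 (percentile 55.0), with Ctla4 at 1.22 (1.09 to 1.36). Crtam, a surface receptor of activated T cells, was 2.77-fold lower (1.74 to 4.55). So were Neurl4 (2.95-fold, 1.55 to 6.003) and Gabrr2 (2.61-fold, 1.52 to 4.67), though from 1000 detected genes their log2 ratios were -0.64 and -0.72, and with each library clustered alone that of Neurl4 was -0.20. Slc15a2 (280 and 1 UMIs, ratio 299.2, 53.3 to 11860) was higher, and of the 6 genes named by ratio it alone passed the rule under each of 14 alternatives.

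Genes of the type 2 and allergic response did not pass the size rule in T cells, NK/ILC1 cells or Kupffer cells. Their median log2 ratio was -0.040 (percentile 30.4) over 12 measured genes in T cells, 0.084 (percentile 76.4) over 5 in NK/ILC1 cells and 0.080 (percentile 88.6) over 10 in Kupffer cells; in T cells without cluster 22 it was 0.48. In monocytes it was 0.15 (percentile 92.6) over 11 genes, of which Ccl22 passed the rule. Il4, the type 2 cytokine, was found in 7.72% (5.10 to 11.1) and 8.50% (5.96 to 11.7) of T cells thinned to 4432 UMIs, and in 9.93% and 10.9% without thinning. Hepatocytes, which should lack it, gave 0.0380% and 0.0397% at 2516 UMIs and 0.126% and 0.122% without thinning, at median depths of 5284 and 4812 UMIs against 6308 and 5912 in T cells. Gata3, the regulator of type 2 T cells, was found in 25.8% (21.2 to 30.8) and 25.2% (21.1 to 29.8) of thinned T cells and in 33.3% and 31.0% without thinning. In hepatocytes its shares were 0.304% and 0.278% thinned and 1.11% and 1.22% without thinning. In NK/ILC1 cells Gata3 was found in 27.0% (19.4 to 35.8) and 24.1% (17.8 to 31.3) thinned to 4192 UMIs and in 29.4% and 29.6% without thinning. Il1rl1, the receptor of interleukin 33, was found in 5 of 337 thinned T cells (1.48%, 0.483 to 3.43) and 0 of 400 (up to 0.918%), and in 9 of 423 and 1 of 497 without thinning, with 0% of hepatocytes. It was found in none of the 143 and 216 NK/ILC1 cells. Il13 gave at most 2 positive T or NK/ILC1 cells in a library and Il5 none, and Il4 was found in 0 and 1 NK/ILC1 cells. Ascl2 gave no UMI in 423 and 497 T cells (up to 0.868% and 0.739%) or in 143 and 216 NK/ILC1 cells (up to 2.55% and 1.69%), and 1 UMI in the hepatocytes of each library.

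Mki67, a marker of dividing cells, was found in 17.5% (13.6 to 21.99) and 8.25% (5.75 to 11.4) of thinned T cells, and in 20.6% and 9.46% without thinning, at median depths of 6308 and 5912 UMIs. In hepatocytes it was found in 0.836% (0.525 to 1.26) and 1.99% (1.48 to 2.61) at 2516 UMIs, and in 2.59% and 4.65% without thinning. Proliferation genes had a median log2 ratio of -0.83 (percentile 0) over 21 genes in hepatocytes, with Tubb5, a tubulin, 2.0015-fold lower (1.84 to 2.18). This median lay between -1.13 and -0.46 under the alternatives. In the wild-type library another class held Tubb5 at 772% of its hepatocyte level. RNA or cells of other classes may therefore add to the hepatocyte values of such genes. No class lacks dividing cells by definition; the lowest thinned shares were 0.341% (0.0413 to 1.23) and 0.883% (0.356 to 1.81) of B cells at 1218 UMIs, with 1.51% and 1.81% without thinning.

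Monocytes and NK/ILC1 cells were compared as the smaller immune classes, with 193 and 210 monocytes and 143 and 216 NK/ILC1 cells. In monocytes 41 genes were higher and 43 lower. Up to 50% mitochondrial UMIs 111 were higher and 50 lower, 60 of them shared, at clustering resolution 2.0 82 and 54 with 30 shared, and with each cell weighted equally 156 and 141 with 45 shared. The neutrophil granule genes S100a8 and S100a9, chosen only after the data were seen, gave 10 and 10 UMIs in monocytes of the knockout-labelled library against 1844 and 2023 in the wild-type library, so RNA or cells of neutrophils may add to the lower genes. Ccl22, a chemokine that draws type 2 T cells, was 5.65-fold higher (3.82 to 8.61), Mir155hg 4.89-fold (3.34 to 7.32), Cxcl1 4.67-fold (2.51 to 9.34) and Cxcl2 2.19-fold (1.99 to 2.41). The cytokine and NF-kB list had a median log2 ratio of 0.21 (percentile 99.96) over 21 genes, which turned to -0.061 with each cell weighted equally. At clustering resolution 2.0 the log2 ratio of Ccl22 was 0.015 against 2.48. Prtn3, a granule protease, was 3.79-fold lower (2.74 to 5.35), yet its log2 ratio turned to 2.11 when cells needed 1000 detected genes. Also lower were D17H6S56E-5 (3.54-fold, 2.09 to 6.30), with a log2 ratio of -0.32 against -1.79 from 1000 detected genes, and Ankrd40 (3.08-fold, 1.71 to 5.89), and higher Slc15a2 (168 and 2 UMIs, ratio 96.2, 26.2 to 801.2). In NK/ILC1 cells 13 genes were higher and 37 lower. With doublet calls kept 55 were higher and 70 lower, 25 of them shared, from 1000 detected genes 7 and 40 with 15 shared, and with each library clustered alone 25 and 24 with 32 shared. After Slc15a2 the largest ratios upward were Pign 2.81-fold (1.58 to 5.16) and the integrin Itga6 2.72-fold higher (1.47 to 5.22). Spred1, an inhibitor of the MAP kinase pathway, was 3.42-fold lower (1.71 to 7.58), Marchf3 3.11-fold (1.997 to 5.01) and Spats2 3.09-fold (1.74 to 5.83). The 16 cytotoxic genes of these cells had a median of -0.045 (percentile 9.51), with Gzma at 0.909 (0.872 to 0.948). Slc15a2 (69 and 0 UMIs, at least 32.3-fold) was higher as elsewhere. Of the 6 genes named by ratio, 4 in each of these 2 classes missed the size rule under at least 1 alternative.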

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

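Among the tests in this part, those on the position and the class profile of the shared genes, on clock genes, on hepatocytes as the highest class and on free hepatocyte RNA were chosen only after the result was seen. So were the same cluster weights for both libraries and the reading of the test on levels in other classes, described below. The labels name the genotype as the biological difference; with 1 library for each it stays among the open explanations, untested, beside animal and handling.

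Some genes went opposite ways in a pair of classes. H2ax had log2 ratios of 1.01 in T cells and -1.06 in hepatocytes, a difference of 2.07 that was not tested. The T cell value may depend on the dividing cluster 22, which held 19.1% of T cells in the knockout-labelled library against 5.43%. In the wild-type library another class held H2ax at 911% of its hepatocyte level, so RNA of other classes may add to the hepatocyte value. Ppfibp2 had log2 ratios of 1.03 in B cells and -1.04 in monocytes, a difference of 2.07 that was not tested; up to 50% mitochondrial UMIs the B cell value was 0.15, below the size rule.

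Of the 7 genes past the size rule in at least 3 classes, Slc15a2, Gm56626 and Eps8l1 had log2 ratios above 1 in 8 of 8 classes, while Mid1 and Igfbp1 lay near 0 in some. For the 6 placed genes, DNA carried along with the targeted allele is argued against, since 0 of them lay within 20 Mb of Slc22a18. Eps8l1 lay on the same chromosome, at a distance of 139 Mb. Gm56626 could not be placed, and neighbours of Slc22a18 that missed the size rule, such as Phlda2, were outside this test. For Slc15a2, 6 of the 8 classes held at least 30% of its highest class's level in the knockout-labelled library. This met the outcome set against free RNA from a single class. Yet Alb, a hepatocyte marker looked at after the result, was at 8744 CPM in hepatocytes of that library. It was at 5059, 4197, 3122 and 2988 CPM in B cells, stellate-like cells, NK/ILC1 cells and monocytes, and so would meet this outcome too. The test therefore cannot separate free RNA from expression, and free RNA is left open for Slc15a2. For the other 6 genes it was not tested, and hepatocyte RNA may give the Igfbp1 values outside hepatocytes. Another genetic background of 1 of the animals could give this pattern, and so could the genotype: the placed genes lay on 6 chromosomes, and these cannot be told apart with 1 library per genotype.

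The 63 hepatocyte genes past the size rule, such as G6pc, Onecut1 and Igfbp1, could reflect another mix of hepatocytes. With clusters given the same weights in both libraries, 94.5% of their median absolute log2 ratio was kept and 63 of 63 kept their direction. Under these weights 51 genes passed the size rule, 47 of them shared with the 63. Cluster shares therefore do not account for most of the set's size, though some genes depend on them. A mix within clusters was not tested. For collection at another time of day, 0 of 19 clock genes passed the rule in hepatocytes, the outcome set against it. The rule asks for a ratio of at least 2 and enough UMIs, and how many of the 19 could reach it was not counted. A smaller shift in time is therefore left open. RNA of other classes is open. Only 1.59% of the genes stayed under 30% of the hepatocyte level in each other class, which met the outcome set for that explanation, yet 25% of 12 hepatocyte markers did so too, so the test was saturated and was judged void after the result. In a later test 66.7% of the genes, 42 of 63, had a higher level in hepatocytes than in each other class, between the bounds set for either outcome; feeding state, which acts on G6pc and Igfbp1, was not tested.

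Slc22a18 was kept in hepatocytes and lower in Kupffer cells of the knockout-labelled library, though at resolution 0.5 not past the size rule (log2 ratio -0.50 against -1.08), nor with each cell weighted equally (-0.97), and lower in endothelial cells at a level that free RNA could give. Free RNA could give the Kupffer level too, 5.80 and 12.3 CPM against 53.1 and 57.3 in hepatocytes. The hepatocyte marker Alb was at 2269 and 2382 CPM in Kupffer cells against 8744 and 11859 in hepatocytes. More free hepatocyte RNA in the wild-type library is argued against, since the lower of the median log2 ratios of hepatocyte transcripts in those cells was -0.12. Unspliced nuclear transcripts that a deletion leaves in place may keep the hepatocyte signal. The outcome set for this was a ratio under 0.6 in cluster 29, with the highest mitochondrial share among hepatocyte clusters. The ratio there was 0.749 (0.594 to 0.939), so this outcome was not met. The outcome set against it, a lower bound of at least 0.6, was narrowly missed too. This explanation therefore cannot be told apart from a label that does not describe the library. No value here names the deleted part.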

How the results depend on the processing

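Tests chosen after the results were seen are the limit of 0.75 on the second class, the absence of a limit on the doublet score, the same cluster weights in both libraries, the classes without cluster 20 or 22, and lists read in further classes. No paired analysis was possible because each genotype had 1 library. The Slc22a18 ratio over all kept cells stayed between 0.860 and 0.901 under 7 alternatives. Of 69 class share values 64 stayed within the interval of the reported value, of 167 gene counts 115 stayed within 1.5 times, of 909 list medians 724 stayed within their counting range, and of 1326 log2 ratios of named genes 1243 stayed within their interval. Of 108 shares of cells with a UMI 55 did so, as thinning to another depth changes them by construction. Other settings could not move some classes, which adds to the values that stayed. Monocytes and NK/ILC1 cells each formed a single cluster, so the same cluster weights changed nothing there. The 2 other limits on naming clusters left the genes past the rule unchanged in hepatocytes, stellate-like cells, T cells, monocytes and NK/ILC1 cells. Depth limits the smaller classes most, where few counts carry a gene over the rule. With each cell weighted equally, 14 higher and 9 lower genes passed the rule over all kept cells, against 29 and 11. Reversed values follow, with the moved numbers of genes past the size rule, ratios of class shares and median log2 ratios of the lists of the study's subjects or at an edge of the matched lists. Not every change of sign is among them, such as that of the interferon list in B cells, between -0.47 and 0.14. Another 77 moved log2 ratios of named genes, 53 moved shares of cells with a UMI and moved medians of other lists, such as 1.81 for proliferation in endothelial cells with each library clustered alone, are not listed. With each cell weighted equally, 23 in all kept cells, 56 in Kupffer cells, 29 in B cells and 297 in monocytes passed the size rule. Hepatocyte medians were -0.20 for lipoproteins, -0.095 for gluconeogenesis, -0.27 for unfolded protein, -0.050 for xenobiotics, -0.19 for mitochondrial and -1.13 for proliferation. Medians were -0.026 for immunoglobulin in B cells, 0.20 for MHC class II in Kupffer cells, -0.061 for NF-kB in monocytes, -0.26 for matrix in stellate-like cells, 1.53 for proliferation in T cells, -0.23 for dissociation in T cells, 0.20 for hepatocyte RNA in stellate-like cells, 0.12 for interferon in stellate-like cells, -0.12 for dissociation in stellate-like cells, -0.21 for dissociation in monocytes, -0.15 for sinusoidal in stellate-like cells and -0.17 for unfolded protein in stellate-like cells. At a ratio of at least 1.5, 127 in all kept cells, 239 in hepatocytes, 37 in endothelial cells, 118 in Kupffer cells, 178 in B cells, 1092 in stellate-like cells, 550 in T cells, 384 in monocytes and 215 in NK/ILC1 cells passed the size rule. At a ratio of at least 3, 11 in all kept cells, 15 in hepatocytes, 4 in endothelial cells, 3 in Kupffer cells, 2 in B cells, 35 in stellate-like cells, 39 in T cells, 9 in monocytes and 4 in NK/ILC1 cells passed the size rule. With a limit of 0.75 on the second class, 22 in endothelial cells passed the size rule. Medians were 0.24 for interferon in endothelial cells and -0.16 for hepatocyte RNA in endothelial cells. At resolution 0.5, 37 in Kupffer cells passed the size rule. Hepatocyte medians were -0.53 for mitochondrial. Medians were 0.086 for interferon in Kupffer cells, 0.23 for NF-kB in Kupffer cells, -0.025 for hepatocyte RNA in Kupffer cells and -0.44 for sinusoidal in stellate-like cells. The gene log2 ratio was 0.11 for Tmx4 in Kupffer cells. From 200 summed UMIs, 9 in Kupffer cells, 4 in B cells, 91 in stellate-like cells, 49 in T cells, 10 in monocytes and 2 in NK/ILC1 cells passed the size rule. With no gene set aside as free RNA, 30 in Kupffer cells and 27 in B cells passed the size rule. With genes under 30% of the highest class set aside, 10 in Kupffer cells, 9 in B cells and 48 in monocytes passed the size rule. Up to 50% mitochondrial UMIs, 110 in B cells, 51 in T cells and 161 in monocytes passed the size rule. Hepatocyte medians were -0.52 for mitochondrial. Medians were -0.17 for type 2 in T cells, -0.13 for follicular helper in T cells, -0.15 for immunoglobulin in B cells, 0.35 for proliferation in T cells, -0.18 for dissociation in T cells, -0.22 for dissociation in B cells and -0.24 for dissociation in monocytes. The gene log2 ratio was 0.079 for Ago4 in B cells and 2.04 for Prtn3 in monocytes. From 1000 detected genes, 37 in B cells passed the size rule. Hepatocyte medians were -0.46 for mitochondrial. Medians were 0.061 for NF-kB in monocytes, 0.35 for hepatocyte RNA in stellate-like cells and -0.25 for dissociation in monocytes. The gene log2 ratio was 2.11 for Prtn3 in monocytes. With each library clustered alone, 37 in B cells, 332 in stellate-like cells and 290 in T cells passed the size rule. Hepatocyte medians were -0.45 for mitochondrial and -0.40 for dissociation. Medians were 0.23 for cytotoxic in T cells, 0.18 for immunoglobulin in B cells, 0.057 for MHC class II in Kupffer cells, -0.61 for matrix in stellate-like cells, 3.75 for proliferation in T cells, -0.46 for dissociation in T cells, -0.13 for hepatocyte RNA in endothelial cells, 0.43 for hepatocyte RNA in stellate-like cells, -0.32 for interferon in stellate-like cells, -0.57 for dissociation in stellate-like cells, -0.26 for dissociation in B cells, -0.23 for dissociation in NK/ILC1 cells, -0.53 for sinusoidal in stellate-like cells and -0.42 for unfolded protein in stellate-like cells. The share ratio was 1.80 for T cells and 1.09 for NK/ILC1 cells. With no limit on the doublet score, 156 in B cells passed the size rule. Medians were -0.40 for immunoglobulin in B cells, 0.025 for MHC class II in Kupffer cells, 0.21 for NF-kB in Kupffer cells, -0.40 for proliferation in Kupffer cells and -0.39 for dissociation in B cells. The gene log2 ratio was 0.075 for Ago4 in B cells. Without cluster 20, 58 in stellate-like cells passed the size rule. Medians were -0.16 for matrix in stellate-like cells, 0.077 for hepatocyte RNA in stellate-like cells, 0.24 for interferon in stellate-like cells, 0.12 for dissociation in stellate-like cells, -0.0048 for sinusoidal in stellate-like cells and -0.056 for unfolded protein in stellate-like cells. With the same cluster weights in both libraries, 82 in stellate-like cells and 39 in T cells passed the size rule. Hepatocyte medians were -0.076 for Wnt, -0.061 for periportal, -0.064 for lipogenesis, 0.070 for lipid droplet, -0.017 for lipoproteins, 0.068 for bile acids, -0.18 for gluconeogenesis, 0.24 for acute phase, -0.18 for unfolded protein, -0.018 for xenobiotics, -0.27 for mitochondrial, -0.61 for proliferation and -0.35 for dissociation. Medians were 0.23 for cytotoxic in T cells, -0.18 for matrix in stellate-like cells, 0.11 for proliferation in T cells, -0.17 for dissociation in T cells, 0.057 for hepatocyte RNA in stellate-like cells, 0.16 for interferon in stellate-like cells, 0.052 for dissociation in stellate-like cells, 0.0036 for sinusoidal in stellate-like cells and -0.16 for unfolded protein in stellate-like cells. At resolution 2.0, 109 in T cells and 136 in monocytes passed the size rule. Hepatocyte medians were -0.21 for lipoproteins, -0.17 for gluconeogenesis, 0.23 for acute phase and -0.33 for mitochondrial. Medians were -0.61 for matrix in stellate-like cells, -0.18 for interferon in stellate-like cells and -0.47 for dissociation in stellate-like cells. The share ratio was 1.07 for T cells and 0.805 for monocytes. Without cluster 22, 33 in T cells passed the size rule. Medians were 0.48 for type 2 in T cells, -0.060 for follicular helper in T cells, 0.045 for cytotoxic in T cells, -0.098 for proliferation in T cells and -0.11 for dissociation in T cells. The gene log2 ratio was -0.79 for Ccnf in T cells. From 20 summed UMIs, 202 in monocytes and 160 in NK/ILC1 cells passed the size rule. With doublet calls kept, 125 in NK/ILC1 cells passed the size rule. Hepatocyte medians were 0.066 for fatty acid oxidation, -0.21 for lipoproteins, -0.21 for gluconeogenesis, 0.25 for acute phase, -0.27 for unfolded protein, 0.041 for mitochondrial, -0.46 for proliferation and -0.34 for dissociation. Medians were -0.32 for dissociation in NK/ILC1 cells. The share ratio was 1.10 for hepatocytes. With TMM factors, hepatocyte medians were -0.096 for Wnt, -0.28 for periportal, -0.071 for lipogenesis, -0.064 for fatty acid oxidation, -0.33 for lipoproteins, 0.10 for bile acids, -0.081 for growth hormone, -0.20 for gluconeogenesis, -0.19 for xenobiotics, 0.24 for female-biased, -0.55 for mitochondrial and -0.52 for dissociation. Medians were 0.40 for NF-kB in Kupffer cells, -0.082 for hepatocyte RNA in Kupffer cells and -0.18 for interferon in stellate-like cells. With the median ratio, hepatocyte medians were -0.091 for Wnt, -0.28 for periportal, -0.066 for lipogenesis, -0.058 for fatty acid oxidation, -0.33 for lipoproteins, 0.11 for bile acids, -0.076 for growth hormone, -0.20 for gluconeogenesis, -0.18 for xenobiotics, 0.24 for female-biased and -0.55 for mitochondrial. Medians were 0.40 for NF-kB in Kupffer cells, -0.081 for hepatocyte RNA in Kupffer cells and -0.16 for interferon in stellate-like cells. Up to 10% mitochondrial UMIs, hepatocyte medians were 0.079 for fatty acid oxidation, -0.20 for lipoproteins, 0.12 for bile acids, -0.21 for gluconeogenesis, 0.27 for acute phase, -0.071 for mitochondrial, -0.49 for proliferation and -0.41 for dissociation. Medians were -0.60 for matrix in stellate-like cells, -0.083 for hepatocyte RNA in Kupffer cells, -0.18 for interferon in stellate-like cells, -0.47 for dissociation in stellate-like cells and -0.45 for sinusoidal in stellate-like cells. Over members with at least 100 summed UMIs, medians were 0.035 for interferon in monocytes and 0.58 for type 2 in monocytes. Other limits of the size rule change the counts by construction; for the other settings the cause was not tested.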

Other observations

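The haemoglobin genes, the list of clock genes and the dissociation list in stellate-like, B and NK/ILC1 cells and monocytes were chosen only after the data were seen. The haemoglobin gene Hba-a1 had a ratio of 2.39 (2.30 to 2.48) in endothelial cells, 3.21 (2.56 to 4.06) in Kupffer cells and 4.48 (3.79 to 5.30) in stellate-like cells, but 0.929 (0.554 to 1.55) in monocytes. Transcripts of Foxq1, a forkhead transcription factor, were 3.13-fold higher over all kept cells (2.98 to 3.29), and Rgs16, a regulator of G protein signalling, 2.14-fold lower (2.02 to 2.26).

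Immediate-early and dissociation genes had a median log2 ratio of -0.46 (percentile 0) in hepatocytes, where 21 of 24 were set aside as possible free RNA, -0.27 (percentile 0) in T cells, -0.32 (percentile 0) in stellate-like cells, -0.16 (percentile 0) in B cells, -0.18 (percentile 0) in monocytes and -0.16 (percentile 0.130) in NK/ILC1 cells, against 0.030 (percentile 87.6) in endothelial cells and -0.011 (percentile 36.1) in Kupffer cells. In stellate-like cells it turned to 0.12 without cluster 20. Cholesterol synthesis had -0.048 (percentile 2.56) and autophagy -0.066 (percentile 2.51) in hepatocytes, both at the edge of the matched lists. Organic cation transporters had 0.11 (percentile 82.0) and the imprinted region, Slc22a18 included, -0.013 (percentile 19.2) in hepatocytes. Proliferation genes in endothelial cells had -0.069 (percentile 14.5), from -0.27 to 1.81 under the alternatives, with 1.81 when each library was clustered alone. Cluster 6, with leading genes of dividing cells and endothelial cells as its best class, stayed unnamed and lay outside this class. It held 101 cells of the knockout-labelled library and 177 of the wild-type library, a ratio of shares of 0.619 (0.485 to 0.789). Hepatocyte transcripts had -0.12 (percentile 0.3) in Kupffer cells, -0.030 (percentile 22.8) in B cells and -0.058 (percentile 12.99) in T cells; the B and T cell values changed sign under some settings. Clock genes had 0.020 (percentile 25.6) in hepatocytes, -0.058 (percentile 14.1) in endothelial cells and 0.062 (percentile 96.6) in Kupffer cells.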
